A study of Homo sapiens with 6 samples.

How the data were processed

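Total RNA from cultures of parental SET-2 cells and of their OTX P/R derivative, grown without drug in RPMI medium with fetal bovine serum, was sequenced in 6 libraries, 3 per group. Per the submitters' processing notes, the authors used Trim Galore, HISAT2 and StringTie with the human build hg19; versions are not given in the sources used here. The deposited values are a signal, the StringTie abundance per gene on a linear scale, and the sources used here do not say whether it is FPKM or TPM. The sorted values of the libraries differed by at most 0.243% at values of 1 or more, which shows that the authors' table is quantile-normalized. In such a table every library has the same set of values, so a value tells the rank of a gene within its library, differences in total RNA or in depth are not kept, and a change in a few abundant genes moves the ranks of others. The sequencing depth is therefore unknown, and no counting intervals or floors are given.

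The table held 19785 genes, of which 6 had a missing value in some library and were left out. In 28 rows the symbol had been turned into a number, and 78 rows shared a symbol with another row. Identifiers were matched without version to GENCODE v29 for 19534 genes, 19443 of them protein-coding. That annotation is on GRCh38 and not on the authors' build, so it gave only chromosomes, the order of neighbouring genes, transcript GC content and transcript length. A value of 0 in every library was found for 2412 genes.

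Groups were taken from the sample titles. The values were transformed as log2(value + 1), and the 10741 genes with a mean over the libraries of at least 1 were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance prior that follows the mean, two-sided, Benjamini-Hochberg over all genes tested). A gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and means and SDs are on the linear scale. Exact permutation of 3 libraries against 3 cannot give a two-sided p under 0.1, so p-values for single genes come only from the limma model and measure the spread between these cultures.

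Gene lists, 38 in all, were fixed before the data were examined, as were the tests of genes and lists, the alternatives listed below as fixed in advance and the rule for named genes. The rule takes the 4 axis genes; the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 in the higher group and no overlap between groups, leaving out small RNAs, uncharacterized loci and antisense genes; and up to 3 called members per direction in each list. List members that did not pass may be given with their values. Some genes that the rule covers are not reported here. Lists were tested with limma's camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists with at least 5 tested members, and again with an estimated correlation. A repeated symbol was represented by its row with the higher mean.

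Stretches of neighbouring genes were sought with a running median of the log2 fold changes over 25 tested genes along each chromosome; a stretch is at least 25 consecutive genes with a running median of 0.3 or more in size. The alternatives fixed in advance were a pseudocount of 0.1 or 5, no filter or a minimum mean of 5, a prior without trend, a robust prior, centring on the median, the replicate number as a block, each library left out, repeated symbols summed, and the estimated correlation. The search for stretches, leaving out the genes in them and ranking the table again without HBE1 were added after the data were seen. A test of the share of genes on the side of each stretch was run and then dropped, because the definition of a stretch largely fixes its outcome.

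The procedures were tested on simulated data with the means and within-group spreads of the 10741 tested genes, of which 200 were changed. Genes were drawn independently, and far fewer were changed than the 3879 called in the real data. The shares recovered therefore need not carry over to the real comparison. At a fold of 1.5 the fit recovered 64.2% of the changed genes, at 2 it recovered 82.1% and at 4 it recovered 92.4%, with 11 unchanged genes among 170 calls. Tables were prepared with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and plots drawn with Matplotlib 3.10.9.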

Results

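RNA sequencing of SET-2 cells was compared between the parental line and a derivative that persisted in and became resistant to OTX. SET-2 is an established leukemia cell line of megakaryoblastic character that the labels describe as secondary acute myeloid leukemia. OTX is read here as the BET inhibitor birabresib; BET proteins are bromodomain readers of acetylated histones that sustain transcription of MYC and other genes. Each group had 3 libraries, described as biologic replicates, from exponentially growing untreated cultures, so the comparison is between the lines without drug. The labels name 1 derivative, so what came with resistance cannot be told apart from other differences between the lines. The table gave 1 normalized abundance per gene and library for 19785 genes, and 10741 genes with a mean of at least 1 were tested. The sum of the values was nearly equal in all libraries, from 419375 to 419437, because of the normalization, and the sequencing depth is unknown. Correlations of log2 values over the tested genes were 0.986 to 0.988 within the groups and 0.948 to 0.949 between them, and principal component 1 held 70.7% of the variance.

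The OTX P/R cells differed from the parental cells in 36.1% of the tested genes, 1998 higher and 1881 lower. A fold of at least 1.5 was reached by 727 of the higher and 842 of the lower genes. The largest rise was that of ID4, a helix-loop-helix inhibitor of transcription factors, from a mean of 0.125 ± 0.0829 to 45.9 ± 1.69 (SD, n = 3 per group; log2 fold change 5.39 ± 0.07 SE). ID4 lies in a stretch of chromosome 6 whose genes were higher together. HTRA3, a secreted serine protease, stood at 22.1 ± 0.872 against 0.560 ± 0.0799, and NNMT, which methylates nicotinamide, at 20.2 ± 0.826 against 1.66 ± 0.155. EPB42, a protein of the red cell membrane skeleton, rose by a log2 fold change of 2.94 ± 0.16. EXOC6B, GDF3, JAM3, GJA5, SP6, PLEKHA7, MSX1 and NID1 completed the 12 largest rises, with log2 fold changes from 2.66 for NID1 to 3.98 for EXOC6B. MSX1 was listed at 0 in the 3 parental libraries, so no fold is given for it, and its OTX P/R mean was 5.38 ± 0.385.

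Among the 12 largest falls, CTAG2, a cancer-testis antigen, went from 88.2 ± 4.40 to 0.457 ± 0.127 (SD, n = 3 per group; log2 fold change -5.94 ± 0.08 SE). LGALS3BP, a secreted glycoprotein that binds galectin, went from 162.9 ± 19.4 to 3.12 ± 0.573. NMU, a neuropeptide precursor, fell by 4.59 on the log2 scale, and CBFA2T3, a transcriptional corepressor of blood cells, fell by 4.31. SLC16A9, ELAVL4, CSAG1, KCNK1, POPDC3, GPC4, EPS8L3 and MAGEA12 made up the rest, with log2 fold changes from -4.06 for SLC16A9 to -3.08 for MAGEA12. CTAG2, CSAG1 and MAGEA12 belong to families with near-identical copies, between which the authors' counting could split reads. Among all tested genes the libraries of the groups did not overlap in 51.6%, where chance gives 10%.

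**Figure D1:**
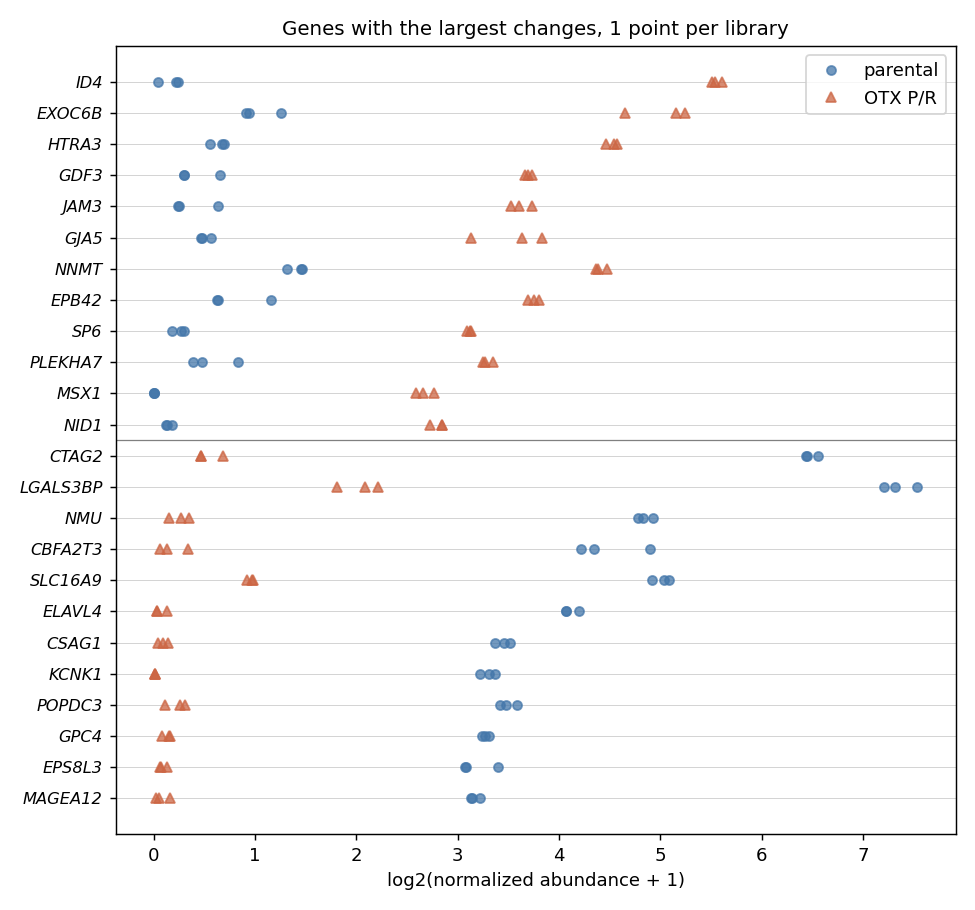
Log2 of the normalized abundance plus 1 (horizontal axis) for the 12 genes with the largest rise (upper part) and the 12 with the largest fall (lower part), 1 point per library, circles for parental and triangles for OTX P/R. The genes were chosen among those without overlap between the groups, and the means are 0.125 and 45.9 for ID4 and 88.2 and 0.457 for CTAG2.

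The title of the series names an axis of beta-catenin, TCF7L2, JMJD6 and MYC, and 1 of these 4 genes passed the test. MYC, on chromosome 8, was higher in OTX P/R cells, at 250.5 ± 21.1 against 184.5 ± 27.0 (SD, n = 3 per group), a log2 fold change of 0.45 ± 0.12 SE with a 95% interval of 0.15 to 0.75 and a limma adjusted p = 0.0336. CTNNB1, which encodes beta-catenin, on chromosome 3, did not pass, at 45.5 ± 1.72 against 40.8 ± 3.95 (log2 fold change 0.16, interval -0.03 to 0.35, adjusted p = 0.173). JMJD6, a dioxygenase on chromosome 17, did not pass either, at 18.9 ± 1.85 against 16.9 ± 1.33 (log2 fold change 0.15, interval -0.07 to 0.37, adjusted p = 0.246). TCF7L2, the transcription factor partner of beta-catenin, on chromosome 10, was near the lower end of the tested range, at 1.26 ± 0.335 against 0.761 ± 0.349, and did not pass (log2 fold change 0.37, interval -0.06 to 0.79, adjusted p = 0.151). The same single gene passed when the p-values were adjusted over the list alone, MYC at 0.0431. The MYC call was lost without parental replicate 2 (adjusted p = 0.0643), without OTX P/R replicate 2 (0.0992) or without OTX P/R replicate 3 (0.0951), and when genes of low values were tested too (0.0584), while its log2 fold change ranged from 0.32 to 0.53 over the libraries left out.

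**Figure D2:**
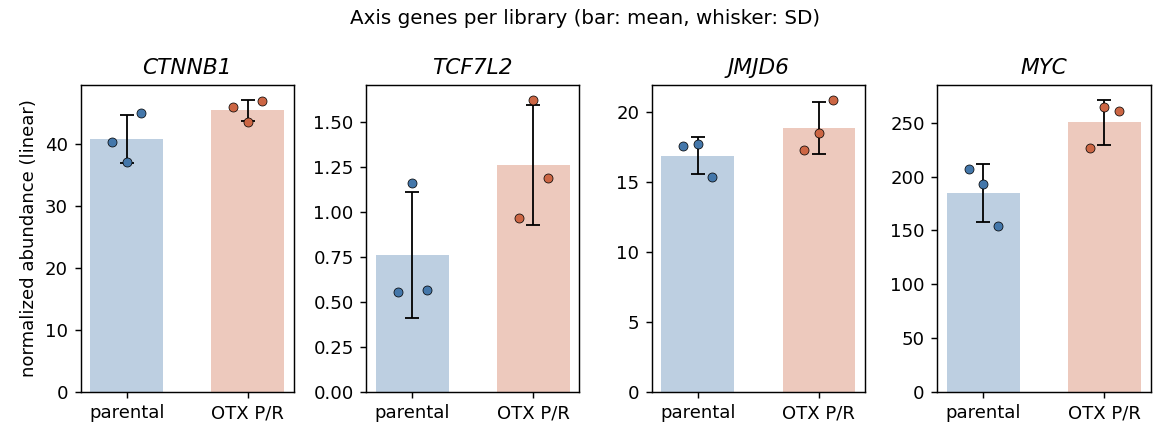
Normalized abundance on a linear scale (vertical axes, each from 0) of the 4 axis genes in parental and OTX P/R cells, with bars for the mean, whiskers for the SD and 1 point per library (n = 3 per group). MYC has means of 184.5 and 250.5 with no overlap between the groups, while the libraries of CTNNB1, TCF7L2 and JMJD6 overlap.

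Genes around Wnt signalling moved in both directions. Of 12 tested Wnt and beta-catenin target genes 3 rose, 4 fell and 5 did not pass, with the same counts adjusted over the list alone. TNFRSF19, a receptor of the TNF family, rose from 0.278 ± 0.0385 to 4.44 ± 0.883 and CD44, a hyaluronan receptor, from 18.2 ± 1.83 to 29.6 ± 4.70. NKD2, an inhibitor of the pathway in a stretch of chromosome 5 whose genes were lower together, fell from 7.25 ± 0.534 to 2.59 ± 0.475, and PPARD from 4.93 ± 0.225 to 2.10 ± 0.214. Of 29 pathway components 9 rose, 4 fell and 16 did not pass, again with the same counts adjusted over the list alone. The receptor FZD5 rose by a log2 fold change of 1.26 and the ligands WNT3 and WNT11 by 1.10 and 0.98, while CSNK1A1, a kinase that primes beta-catenin for degradation, fell by 0.72 and also lies in such a stretch. Neither list passed as a set (camera adjusted p = 0.948 and 0.286).

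Genes tied to MYC and to BET inhibition did not move as sets. Of 66 MYC target genes 15 rose, 8 fell and 43 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.129). ODC1, the rate-limiting enzyme of polyamine synthesis, rose from 174.9 ± 7.65 to 251.7 ± 5.37, and NOP16 and TCOF1, both of ribosome biogenesis, fell by 0.51 and 0.59 on the log2 scale. NOP16 and TCOF1 lie in a stretch of chromosome 5 whose genes were lower together, and 5 of the 8 members that fell lie in such stretches. Without the genes in such stretches, an alternative chosen after the data were seen, the MYC target list passed upward (adjusted p = 0.0178). Of 12 genes known to be lowered by BET inhibition in leukemia 3 rose, 3 fell and 6 did not pass; adjusted over the list alone 5 rose and 3 fell. KIT, a receptor tyrosine kinase, fell from 106.1 ± 8.96 to 54.3 ± 1.30 and CDK6 from 20.4 ± 1.29 to 11.8 ± 1.02. MYC, also a member of this list, and ETV6 rose by log2 fold changes of 0.45 and 0.25, and the median of the list was 0.22. Of 10 genes known to be raised by BET inhibition 5 rose, 4 fell and 1 did not pass; adjusted over the list alone 6 rose and 4 fell. The 5 that rose are all histone genes, among them HIST1H1C, from 20.7 ± 0.791 to 57.8 ± 1.95, and 4 of them lie in a stretch of chromosome 6 that was higher. BCL2L11, a cell death protein, fell by 0.72 and TXNIP by 0.40. Of 31 BET proteins and elongation factors 3 rose, 8 fell and 20 did not pass, with the same counts adjusted over the list alone, and 6 of the 8 that fell lie in stretches of lower genes, MED24 (log2 fold change -1.30) and AFF4 (-0.78) among them. The camera adjusted p was 0.728, 0.280 and 0.380 for these lists.

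Most megakaryocyte and erythroid genes were higher in OTX P/R cells. Of 24 megakaryocyte and platelet genes 16 rose, 4 fell and 4 did not pass, with 17 and 4 adjusted over the list alone. ITGB3, the beta chain of the platelet fibrinogen receptor, rose from 4.83 ± 0.585 to 21.0 ± 1.04. RAB27B, which acts in granule secretion, fell by 1.90 on the log2 scale, and ITGA2B, the partner chain of ITGB3, fell by 0.64 and lies in a stretch of lower genes on chromosome 17. The list passed upward (camera adjusted p = 2.00e-04), and the adjusted p = 0.116 with an estimated correlation. Of 36 erythroid genes 21 rose, 7 fell and 8 did not pass, with 23 and 9 adjusted over the list alone (camera adjusted p = 0.0232; adjusted p = 0.381 with an estimated correlation). Among the globin genes the embryonic HBZ and HBE1 and the adult HBB went the other way. HBB fell by 1.30 on the log2 scale, HBZ fell from 59.9 ± 2.96 to 12.8 ± 1.40, and HBE1, the highest value of each parental library, fell by 2.53 on the log2 scale to 1291 ± 40.2. Because the parental value of HBE1 is set by its rank, the size of its fall is not measured exactly.

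The myelomonocytic, mast cell, stem cell and LSC17 lists did not pass as sets. Of 12 myelomonocytic genes 4 rose, 4 fell and 4 did not pass, with 5 and 5 adjusted over the list alone (camera adjusted p = 0.656). CSF2RA, a chain of the receptor for granulocyte-macrophage colony-stimulating factor, rose by a log2 fold change of 1.12, while ITGAX fell by 1.53 and CD68 by 1.08. Of 10 mast cell and basophil genes 3 rose, 6 fell and 1 did not pass, with the same counts adjusted over the list alone (0.523). CPA3, a mast cell protease, rose from 0.699 ± 0.141 to 7.52 ± 0.0890. Of 17 stem and progenitor cell genes 8 rose, 3 fell and 6 did not pass, with 10 and 3 adjusted over the list alone (0.0691), and the list passed upward without the genes in stretches that shifted together (0.0216), an alternative chosen after the data were seen. CD34 rose from 32.6 ± 3.34 to 63.4 ± 1.63, and CD99 fell from 13.7 ± 0.576 to 5.32 ± 0.903. Of 13 genes of the LSC17 stem cell signature 6 rose, 3 fell and 4 did not pass, with the same counts adjusted over the list alone (0.227). For stromal and endothelial cells 1 gene was tested and rose, for epithelial cells 2 were tested and both rose, and for B and plasma cells 2 of 3 fell, with the same counts adjusted over the list alone and too few members for a set test.

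Most interferon-stimulated and antigen presentation genes were lower in OTX P/R cells. Of 40 interferon-stimulated genes 5 rose, 21 fell and 14 did not pass, with 5 and 25 adjusted over the list alone (camera adjusted p = 3.38e-04; adjusted p = 0.116 with an estimated correlation). IFI27 fell from 4.72 ± 0.690 to 0.620 ± 0.176, while IFITM2 rose by a log2 fold change of 0.94. The 5 tested class II antigen presentation genes fell, over all genes and adjusted over the list alone (camera adjusted p = 1.07e-04; adjusted p = 0.116 with an estimated correlation). CD74, the invariant chain, fell by 2.82 on the log2 scale and lies in a stretch of lower genes on chromosome 5, while HLA-DRA, outside such stretches, went from 4.10 ± 0.159 to 0.250 ± 0.0307. Of 12 class I genes 1 rose, 9 fell and 2 did not pass, with 1 and 10 adjusted over the list alone (camera adjusted p = 0.00119; adjusted p = 0.116 with an estimated correlation). TAPBP, which loads peptides, fell by 0.97 on the log2 scale and the immunoproteasome subunit PSMB10 fell by 1.09, while NLRC5, a transactivator of class I genes, rose by a log2 fold change of 1.14.

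Of 14 NF-kB and inflammatory genes 2 rose, 8 fell and 4 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0290; adjusted p = 0.400 with an estimated correlation). TNFAIP2 fell by 1.15 on the log2 scale and CXCL8, the neutrophil chemokine, fell by 0.88. The call was lost when genes of low values were also tested (adjusted p = 0.170) and with a minimum mean of 5 (0.102). Of 6 T and NK cell markers 1 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00322; adjusted p = 0.125 with an estimated correlation). The cytotoxic protease GZMB went from 4.50 ± 0.880 to 0.205 ± 0.126 and CD3D, of the T cell receptor complex, from 5.24 ± 1.05 to 0.593 ± 0.226, while CD7 rose from 73.4 ± 0.778 to 93.0 ± 5.83. This call was lost when genes of low values were also tested (adjusted p = 0.0999). Of 27 JAK-STAT feedback and target genes 9 rose, 9 fell and 9 did not pass, with 10 and 11 adjusted over the list alone (camera adjusted p = 0.728). SPRY1 and ID1 rose by log2 fold changes of 1.13 and 0.96, and SOCS2, a feedback inhibitor, fell by 0.75.

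Most histone genes were higher, and more S phase genes rose than fell. Of 22 replication-dependent histone genes 15 rose, none fell and 7 did not pass, with 18 and 0 adjusted over the list alone (camera adjusted p = 5.64e-06; adjusted p = 0.125 with an estimated correlation). HIST1H2BC rose from 1.16 ± 0.115 to 6.30 ± 0.527. Of the 22 genes 16 lie in the stretch of higher genes on chromosome 6, and histone gene copies can share reads. Of 44 S phase genes 15 rose, 1 fell and 28 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0148; adjusted p = 0.400 with an estimated correlation). CCNE2, a cyclin of S phase entry, rose by a log2 fold change of 0.93, and the replication licensing factor CDC6, in the chromosome 17 stretch, fell by 0.61 on the log2 scale. Of 52 G2/M genes 16 rose, 4 fell and 32 did not pass, with 16 and 5 adjusted over the list alone (camera adjusted p = 0.0691). CDC20, an activator of the anaphase-promoting complex, rose from 118.2 ± 0.0914 to 190.2 ± 7.53. The G2/M list passed upward with a minimum mean of 5 (adjusted p = 0.0377), without parental replicate 3 (0.0375) and without the genes in the stretches of shifted genes (0.0159).

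More cholesterol synthesis genes rose than fell, and more oxidative phosphorylation genes fell than rose. Of 26 cholesterol synthesis genes 14 rose, 1 fell and 11 did not pass, with 15 and 1 adjusted over the list alone (camera adjusted p = 0.00197; adjusted p = 0.116 with an estimated correlation). INSIG1, a sterol sensor in the chromosome 7 stretch of higher genes, rose by a log2 fold change of 1.69. Of 78 nuclear oxidative phosphorylation genes 5 rose, 20 fell and 53 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00573; adjusted p = 0.478 with an estimated correlation). SDHA, of complex II, fell from 208.9 ± 2.03 to 46.4 ± 7.56, and NDUFA2, of complex I, from 58.9 ± 3.86 to 28.2 ± 2.34, and both lie in stretches of lower genes on chromosome 5. Most of the list moved less, with a median log2 fold change of -0.13, and 16 of the 20 members that fell lie outside the stretches. Of 13 mitochondrially encoded genes 5 rose and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0442; adjusted p = 0.478 with an estimated correlation). MT-ND3 rose from 2028 to 2410.0, a log2 fold change of 0.25. The call was lost without parental replicate 1 (adjusted p = 0.0880), without OTX P/R replicate 1 (0.0761), with a prior that ignores the mean (0.0690), with no filter on low values (0.249), with a minimum mean of 5 (0.0501) and after the table was ranked again without HBE1 (0.524). Of 26 glycolysis genes 5 rose, 7 fell and 14 did not pass, with 6 and 8 adjusted over the list alone (camera adjusted p = 0.903). VEGFA, in this list as a gene of the hypoxia response, rose from 16.7 ± 5.14 to 56.5 ± 16.0. ALDOC, PKM and BNIP3 fell by 0.74, 0.46 and 0.40 on the log2 scale, and the BNIP3 call did not hold with every library left out. ALDOC lies in a stretch of lower genes.

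The remaining lists did not pass as sets. Of 26 apoptosis regulators 3 rose, 7 fell and 16 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.728), and the death receptor TNFRSF10B fell from 4.65 ± 0.751 to 1.75 ± 0.0976. Of 7 ABC drug transporters and related genes 3 fell and 4 did not pass, with the same counts adjusted over the list alone (0.0691). ABCC4, an efflux pump, fell from 52.2 ± 2.56 to 24.9 ± 0.801 and MVP, the major vault protein, fell by 1.14 on the log2 scale, while ABCB1, the multidrug efflux pump, did not pass, with a log2 fold change of -0.17. This list passed downward without parental replicate 2 (adjusted p = 0.0452) and without the genes in the stretches (0.0366). Of 23 adhesion receptors 5 rose, 9 fell and 9 did not pass, with 5 and 10 adjusted over the list alone (0.286), and the integrin chain ITGB7 fell by 2.32 on the log2 scale while ITGA9 rose by a log2 fold change of 1.26. Of 46 chromatin regulators 7 rose, 5 fell and 34 did not pass, with the same counts adjusted over the list alone (0.656). EZH2, the methyltransferase of the Polycomb complex, rose by a log2 fold change of 0.86 and its partner SUZ12 fell by 0.88, EZH2 in the stretch of higher genes on chromosome 7 and SUZ12 in that of lower genes on chromosome 17.

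Of 31 genes of the integrated stress and unfolded protein responses 9 rose, 6 fell and 16 did not pass, with 12 and 6 adjusted over the list alone (camera adjusted p = 0.728). Of 19 heat shock genes 3 rose, 3 fell and 13 did not pass, with the same counts adjusted over the list alone (0.656). Of 22 p53 target genes 3 rose, 3 fell and 16 did not pass, with 1 and 2 adjusted over the list alone (0.991). Of 15 immediate early genes 5 rose, 3 fell and 7 did not pass, with the same counts adjusted over the list alone (0.514), and of 17 TGF-beta and SMAD target genes 6 rose, 2 fell and 9 did not pass, likewise (0.330). Of 79 cytoplasmic ribosomal protein genes 6 rose, 15 fell and 58 did not pass, with 4 and 11 adjusted over the list alone (0.129). The ribosomal genes RPL23 and RPL23A, both in the chromosome 17 stretch, fell by 1.14 and 1.01 on the log2 scale, and 6 of the 15 that fell lie in stretches of lower genes.

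In all, 12 of the 35 lists with at least 5 tested members passed with the preset correlation of camera, and 0 passed with a correlation estimated from the data. That estimate rests on 6 libraries. Of the 3879 changed genes 664 lie in stretches of neighbouring genes that shifted together.

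**Figure D3:**
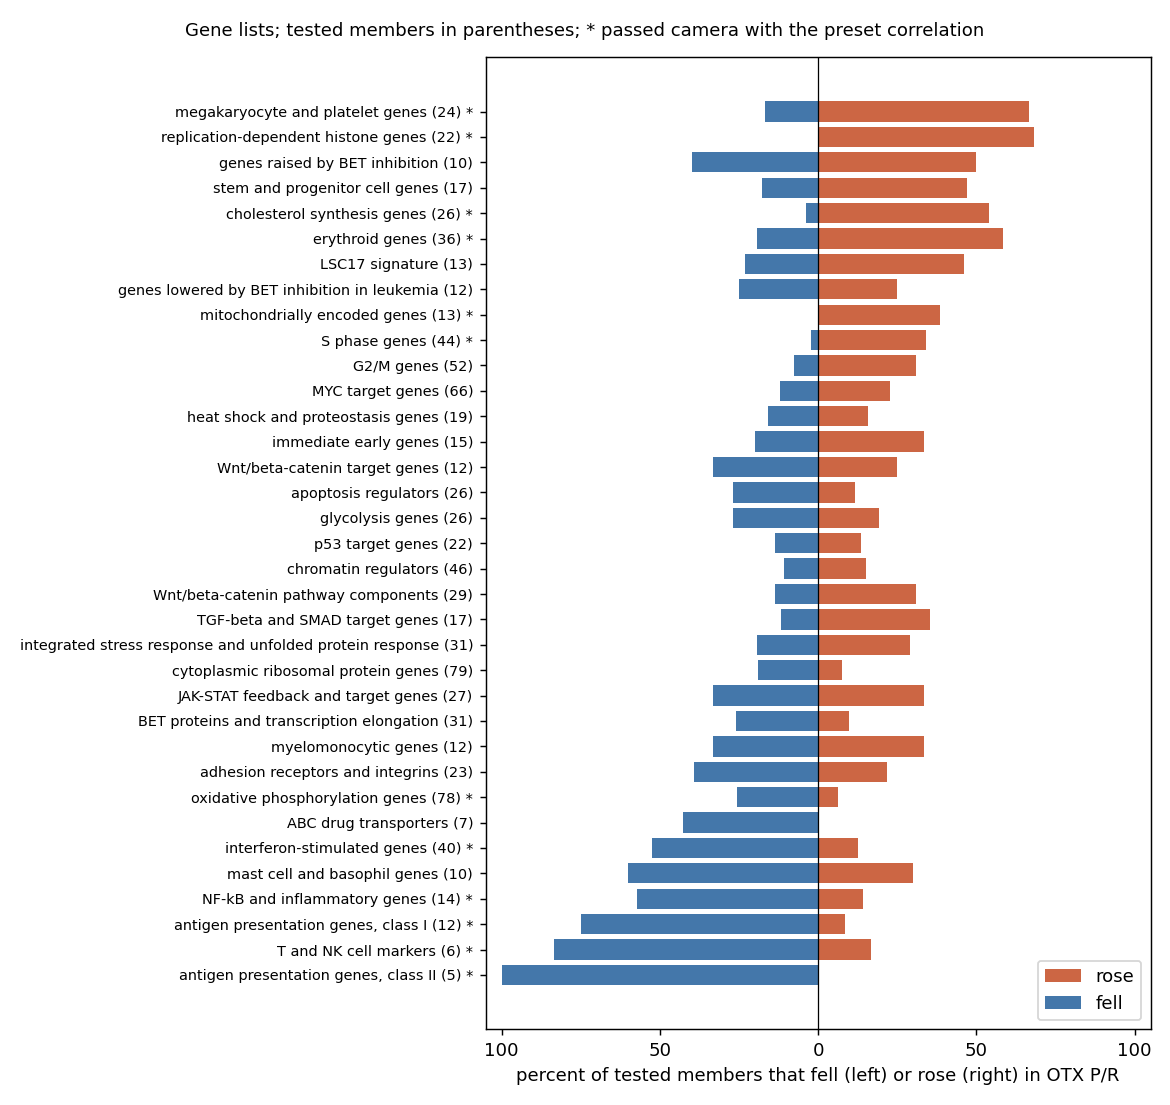
Percent of the tested members of each gene list with at least 5 such members that rose (right) or fell (left) in OTX P/R cells at a limma adjusted p under 0.05, with the number of tested members in parentheses, ordered by the median log2 fold change. A star marks the 12 lists that passed camera with the preset correlation; among these lists the median was lowest for the class II antigen presentation genes, at -2.03, and highest for the megakaryocyte and platelet genes, at 0.68.

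Along the chromosomes, long stretches of neighbouring genes were higher or lower together. On chromosome 7, 236 tested genes from DYNC1I1 to WDR60 had a median log2 fold change of 0.66, with 95.3% of them higher, and on chromosome 6, 68 genes from PHACTR1 to HIST1H2AL had a median of 0.65. On chromosome 17, 181 genes from LGALS9 to HEXIM1 had a median of -0.73, with 96.7% of them lower. On chromosome 5, the medians were -0.49 over 30 genes from CCDC127 to TRIO, -0.74 over 65 genes from IRF1 to PCDHB2 and -0.68 over 138 genes from RELL2 to GNB2L1. On chromosome 19, 42 genes ending at ICAM1 had a median of -0.42 and 80 genes from ICAM3 to NACC1 a median of -0.36. The 3 OTX P/R libraries were alike in this, with shifts from -0.76 to -0.71 on chromosome 17 and from 0.64 to 0.68 on chromosome 7 against the parental mean. Together these 8 stretches hold 840 genes, 7.87% of the 10680 placed, and the order of neighbours is that of the GRCh38 annotation, with no coordinates used. The search for stretches and the naming of their border genes were chosen after the data were seen.

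**Figure D4:**
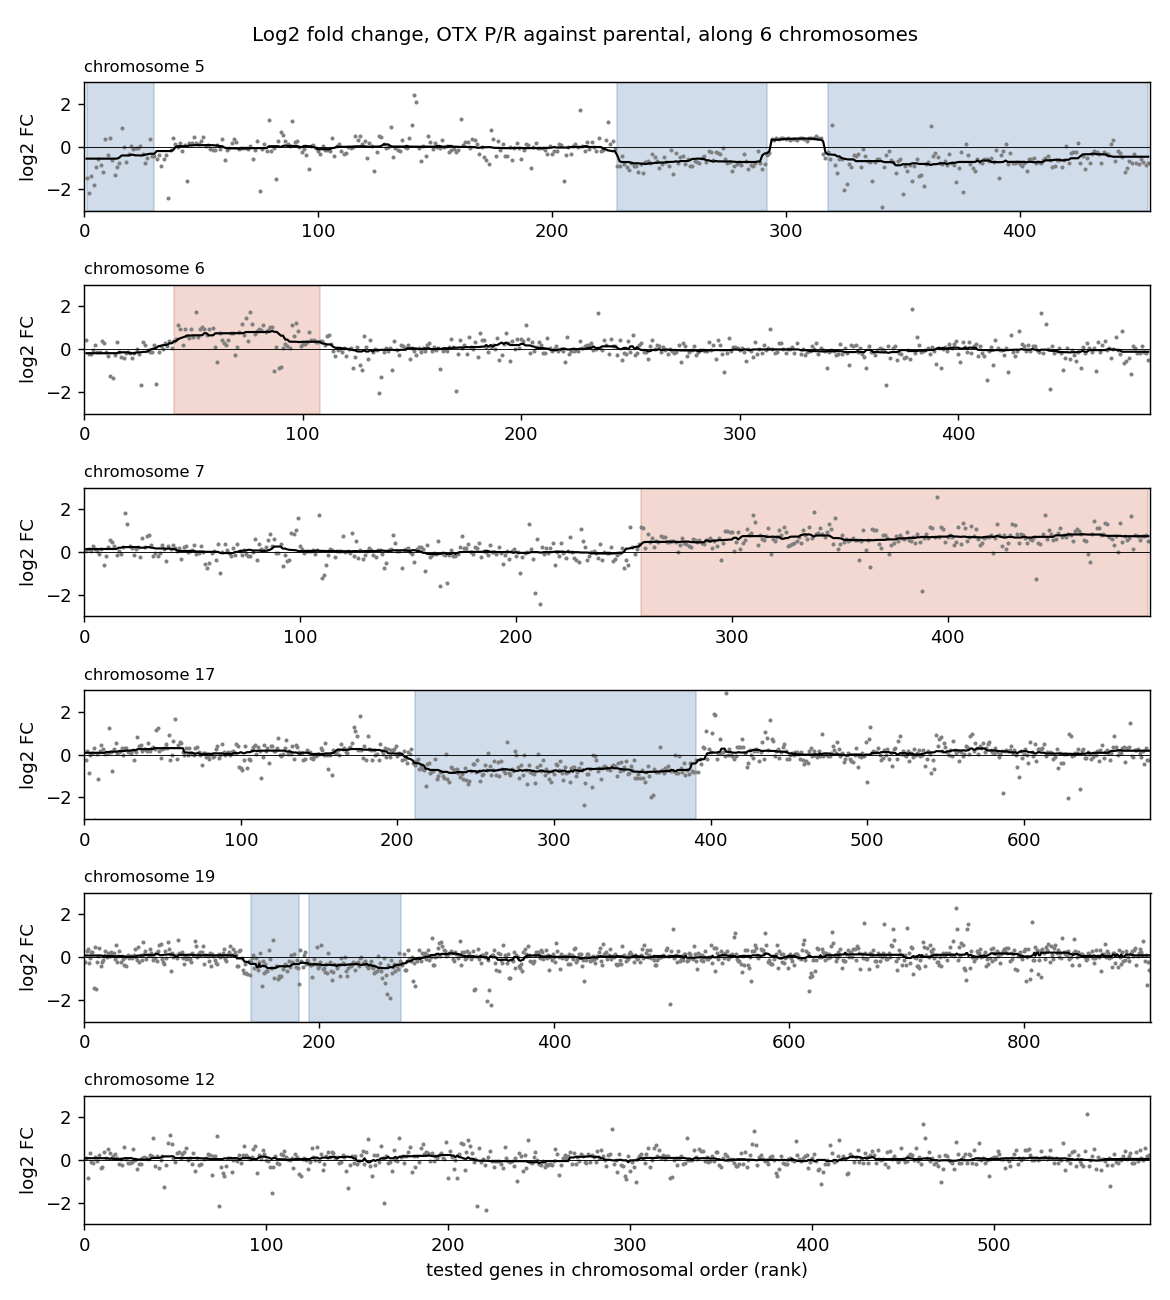
Log2 fold change of OTX P/R against parental (vertical axes) for tested genes in chromosomal order (horizontal axes, rank along each chromosome) on chromosomes 5, 6, 7, 17 and 19 and, as one with no such stretch, 12. Grey points are genes (points beyond the axis limits are not shown), the black line is the running median over 25 genes, and shading marks the stretches, such as the 236 genes of chromosome 7 with a median of 0.66 and the 181 of chromosome 17 with a median of -0.73.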

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

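The counts of higher and lower genes stayed within 1.5 times of the main counts under every alternative run. The counts at 1.5-fold fell with a pseudocount of 5, to 353 higher and 455 lower, since a larger pseudocount shrinks the folds of low genes, and with a minimum mean of 5, to 433 and 537, with fewer genes tested. Leaving out the genes in stretches, chosen after the data were seen, gave 542 higher and 541 lower genes at 1.5-fold, against 727 and 842. That left 9901 of the 10741 genes tested. The stretches held 7.87% of the placed genes but 17.1% of the changed genes, so the drop was larger than the share of genes left out. The mean correlation between groups, 0.948, was 0.925 and 0.962 with pseudocounts of 0.1 and 5, 0.977 with no filter and 0.936 with a minimum mean of 5; the cause was not tested.

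Of the 4 axis genes, 0 passed with no filter on low values, where MYC kept its log2 fold change of 0.45 at an adjusted p of 0.0584, with more genes tested. With each library left out, from 0 to 1 axis genes passed, and the log2 fold change of MYC lay between 0.32 and 0.53. Over its alternatives the adjusted p of MYC was highest, at 0.0992, without OTX P/R replicate 2. The estimated correlation left 0 of the 12 called lists.

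The replicate numbers did not pair the libraries: the correlation of deviations from the group means between same-numbered libraries was -0.06, -0.03 and -2.94e-04, and no library correlated best with its own number. With the number as a replicate block, 1607 genes were higher and 1552 lower, 12 lists passed, MYC (log2 fold change 0.45) had an adjusted p of 0.0793 and TCF7L2 (0.37) passed at 0.0489.

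Of 199 called genes among those covered by the naming rule, 171 kept the call under every alternative that tested them, 26 lost it with some library left out, and 0 changed direction. Apart from the estimated correlation, 3 lists lost a call and 4 gained one under some alternative. Depth is unknown, so no limit from counting can be given.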

Other observations

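The grouping into families was chosen only after the results were seen. Among 272 families, most of them grouped by the stem of the symbol and the 2 given here joined by hand from several stems, cancer-testis antigen genes, normally expressed in the testis and in tumours, fell together. Of 9 tested members 8 fell and 1 rose, with a median log2 fold change of -2.92 (camera adjusted p = 3.31e-06 over the families; adjusted p = 0.989 with an estimated correlation). CTAG1B went from a mean of 6.99 to 0.0566 and MAGEA6 from 4.85 to 0.127, whereas PAGE2B rose from 1.76 to 2.73. This family was put together after CTAG2 and MAGEA12 had been seen among the largest falls, so its p is not independent evidence, and near-identical copies share reads. The 22 tested genes of the gamma protocadherin cluster rose, with a median of 0.39 (camera adjusted p = 6.43e-07; adjusted p = 0.989 with an estimated correlation). They lie between 2 of the stretches of lower genes on chromosome 5 and share their last exons, so they are closer to 1 measurement than to 22.

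The stretches of neighbouring genes that shifted together were weighed first; of these tests the comparison with random orders was chosen only after the result was seen. In 1000 random orders of the genes 0 had such a stretch, which argues against the order of genes by chance. After a smooth fit on GC content and transcript length, every stretch kept at least 93.2% of its median shift, which argues against these properties as the whole source. A difference in the number of DNA copies between the lines would shift genes alike whatever their abundance. Only genes in stretches with a mean of at least 5 were used for this comparison. The ratio of the median shift of the 287 more abundant to the 287 less abundant was 0.938, as such a difference would give. The stretches were chosen for genes that shift alike, which favours such a ratio whatever the cause. The ratio therefore cannot tell causes apart, and a difference in DNA copies stays possible. DNA was not analysed here, and regulation over whole chromosome domains stays open as untested.

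The higher mitochondrially encoded genes were weighed next, by a test written down after the rise but before its own result was seen, and MT-CO2 and MT-ATP6 are named here after their values were seen. HBE1 held rank 1 in the 3 parental libraries and ranks 29 to 33 in OTX P/R, and in the table ranked again without it 1 mitochondrially encoded gene passed where 5 had: MT-ND3, with a log2 fold change of 0.25 ± 0.04 SE before and 0.19 ± 0.04 after, which argues against the rank step left by HBE1 as the whole source of its rise. The call of MT-ND4 ended as its log2 fold change shrank from 0.28 ± 0.05 to 0.11 ± 0.06 (adjusted p = 0.185) and that of MT-ATP6 as its own shrank from 0.17 ± 0.04 to 0.04 ± 0.05 (adjusted p = 0.538), while MT-ND4L, at 0.32 ± 0.10 before and 0.18 ± 0.11 after (adjusted p = 0.240), shrank to a fold near that of MT-ND3 with a wider spread, and its call also ended without parental replicate 1 (adjusted p = 0.0719) or without OTX P/R replicate 1, 2 or 3 (0.110, 0.113 and 0.112). MT-CO2 decides nothing, because it holds rank 1 in all 6 libraries once HBE1 is left out, which fixes its fold. The rank step left by HBE1 may account for part of the rise, and a real rise stays open.

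The gene lists that moved together were weighed against the same stretches; the histone comparison was chosen only after the result was seen. Of the 12 called lists 11 passed without the genes in stretches, and the remaining list, class II antigen presentation, then had too few members to be tested. Most of the 11 had few members to lose. In stretches lay 0 of 6 T and NK cell markers, 0 of 13 mitochondrially encoded genes and 1 of 24 megakaryocyte genes, against 16 of 22 histone genes. For lists with so few members there, the counts themselves argue against the stretches as the source, and the retest could change little. For the histone genes the question stays open. The 6 members outside the stretches had a median log2 fold change of 0.49, just under the 0.5 set as the limit. Of these 6, 3 rose and 0 fell, and they passed upward as a set with the preset correlation (camera adjusted p = 0.0132). Within the chromosome 6 stretch 29 HIST1 genes had a median of 0.80 (quartiles 0.37 and 1.05) beside 0.52 (0.16 and 0.94) for 39 other genes. HIST1 genes are thus 29 of the 68 genes of the stretch, so they helped to define it. The stretch ends at a histone gene, HIST1H2AL, and whether members counted as outside lie near that border was not examined. A shift of the whole stretch and a rise of histone genes by themselves cannot be told apart here, also because the members outside are so few.

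The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. In limma's test only 1 of the 10 splits, the real one, gave as many genes in each of the 4 counts: 1998 higher, 1881 lower, 727 higher and 842 lower at 1.5-fold, where the highest of the other splits gave 0, with 168 to 279 genes at an unadjusted p under 0.05 against 4995 in the real split. Each other split puts libraries of both lines into both groups, so the difference between the lines widens the spread within them. Few or no calls were bound to follow, and these splits do not measure chance. For the lists 1 split, the real one, called 12, and the highest of the others called 4, so camera with the preset correlation called lists in splits where no gene passed. Part of the difference between the lines stays in such splits, so these calls are not a count of false calls.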
